A study of Homo sapiens with 6 samples.

How the data were processed

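Small RNA sequencing was carried out on 6 samples of U2OS, an established human osteosarcoma cell line. The genotype label was LINC00673 for 3 samples and NC for 3, and the replicate numbers 1 to 3 were taken from the sample titles. The design text of the series names wild-type cells and cells that stably carry an shRNA against LINC00673. The LINC00673 label was therefore read as the shRNA cells and NC as the cells they were compared with. The labels do not state whether NC cells were untreated or carried a control construct, though sample titles of both groups start with the same prefix, Lv. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. Per the labels' protocols, RNA was isolated with TRIzol and libraries were prepared with a NEBNext small RNA kit. Adapter ligation in such kits favours some sequences, so levels of different miRNAs do not measure their molar ratio, whereas the same miRNA can be compared between libraries. The labels name no molecular identifiers, so intervals and read floors cover counting error only.

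The authors deposited 1 table of read counts scaled to a common total (CPM) per mature miRNA and library, with 1155 miRNAs. The genome build was hg38, per the submitters' processing notes. The aligner, the counting program, the miRBase release and the treatment of reads that match several miRNAs are not given in the sources used here. Every CPM value above 0 was a whole multiple of 1 step per library (100% of values within 0.1 read), which gave back the reads behind each value. The denominators came to 380298, 742349 and 762663 reads in LINC00673 replicates 1, 2 and 3, and to 483322, 311448 and 295567 reads in NC replicates 1, 2 and 3. The listed miRNAs held 68.6% to 72.0% of the CPM total, so the denominators included reads beyond the rows used here. CPM is a relative measure, and a change in an abundant species shifts the others. A floor of 3 reads corresponded to 3.93 to 10.1 CPM. Among rows above 0 in all 6 libraries, 5 sets (11 rows) had identical values, such as miR-199a-3p and miR-199b-3p, so some reads were listed under more than 1 name. Rows with a 0 in any library were not searched, and only the 5 sets were merged in the alternative below. In the C19MC list, miR-518e-5p, miR-519b-5p, miR-519c-5p, miR-522-5p and miR-523-5p all had a log2 difference of -0.28 and may share reads too.

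Tests were run in limma 3.58.1 (R 4.3.3) on log2(CPM + 1) with an intensity trend in the variance prior, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The 810 miRNAs with a mean of at least 1 CPM over all 6 libraries were tested. Fold changes on this scale understate the change of low miRNAs. Lists of miRNAs were tested with limma's camera at a preset correlation of 0.01, adjusted over the 18 lists with at least 3 tested members among 20 lists. These were the let-7 family, the miR-17-92 cluster and its paralogs, p53-responsive miRNAs, the miR-200 family, mesenchymal and stromal miRNAs, osteoblast-related miRNAs, hypoxia-induced miR-210, the 14q32 imprinted cluster, C19MC, muscle, blood cell and other lineage miRNAs, names that share reads with other structured RNAs, mirtrons and other miRNAs made without Drosha, the miR-23/27/24 clusters, the miR-15/16 family, the miR-181 family, the cluster of miR-183, miR-96 and miR-182, inflammation-induced miRNAs and reported LINC00673 partners. Per-library summaries were compared with exact permutation tests of the group means, two-sided, whose smallest p with 3 against 3 is 0.1. The groups, the limma, camera and permutation tests described above, the lists and the rule for naming miRNAs were fixed before the data were examined. The principal component analysis, the permutation tests of the summed levels of lists and the tests of clusters of neighbouring miRNA genes and of arm ratios were added afterwards.

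The naming rule took miRNAs past the threshold with a mean of at least 10 CPM and no overlap between groups, up to 10 in each direction. Where fewer than 5 passed in a direction, it took the 10 with the smallest p in that direction and a mean of at least 10 CPM, which was the case in both directions here. It also took the 5 most abundant miRNAs, and up to 3 of the most abundant members of each list. It further took every measured member of the list of reported LINC00673 partners, which is not analysed here. Positions are those of the precursor genes in GENCODE release 29 (GRCh38, the same assembly as hg38), matched by name for 1129 of the 1155 miRNAs. The GC content of the arm was estimated for 895 miRNAs from the 5p or 3p side of the annotated precursor, not from the mature sequence.

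Alternative settings fixed beforehand changed the pseudocount, the filter on low values, the scaling, the variance prior and the libraries used, added the replicate number as a block, and replaced limma with edgeR 4.0.16 (quasi-likelihood test, TMM) or DESeq2 1.42.0 on the recovered reads. DESeq2 gave no adjusted p for 597 of the 810 miRNAs. Alternatives chosen after the data were seen were reads thinned to the shallowest library, removal of each library's GC trend, LINC00673 replicates 2 and 3 treated as 1 sample, identical rows merged, and edgeR without each library in turn. Clusters of neighbouring miRNA genes were also tested under each alternative. LINC00673 replicates 2 and 3 were the closest pair of libraries (chi-square per degree of freedom 2.73, against 12.6 to 55.9 for other pairs of the same group). They differed by more than sampling noise (chi-square p = 4.3e-54) and were kept as separate samples. This test covers counting error only, so it cannot show that they came from separate cultures.

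The procedure was tested on simulated counts of 810 miRNAs with the real means and library sizes, of which 200 were changed. All reads were recovered from the simulated CPM (100%). Among miRNAs with a mean of at least 10 CPM, limma recovered 25.5% of 2-fold and 66.7% of 4-fold changes, and edgeR 59.6% and 90.2%. Under 10 CPM, limma recovered 0% of 2-fold and 8.16% of 4-fold changes, and edgeR 0% and 18.4%. The share of false calls was 9.09% for limma and 1.19% for edgeR. The counts were drawn in 1 run, independently per miRNA, with edgeR's own dispersion trend and with no divergent library. These shares therefore do not rank limma and edgeR on the real data.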

Results

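The levels of mature miRNAs were measured by small RNA sequencing in 3 LINC00673 and 3 NC libraries of U2OS osteosarcoma cells. The comparison addressed how depletion of LINC00673, a long intergenic non-coding RNA, alters expression in osteosarcoma cells. The listed miRNAs held 265883, 534807 and 543144 reads in LINC00673 replicates 1, 2 and 3, and 331387, 215496 and 211242 reads in NC replicates 1, 2 and 3. LINC00673 itself was not among the rows of the miRNA table, so the extent of the knockdown was not checked in these data. The LINC00673 gene lies on chromosome 17, from 72403322 to 72592804 (GRCh38, RefSeq annotation), a span of 189483 bp that holds 0 annotated miRNA genes.

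The most abundant miRNA in both groups was miR-21-5p, a widely expressed oncogenic miRNA (MIR21, chromosome 17, 59841266 to 59841337, exonic in VMP1), at 166620.0 ± 9940.3 CPM in LINC00673 and 144959 ± 33294 CPM in NC libraries (SD, n = 3 each). Next by the mean over all 6 libraries came miR-29a-3p, of a family known to target collagen transcripts, at 64452 ± 2820.4 against 60784 ± 3919 CPM. The level of miR-16-5p, which targets cell cycle transcripts, was 47848 ± 638 CPM in LINC00673 and 64441 ± 3922 CPM in NC libraries, where its mean exceeded that of miR-29a-3p. The tumour-suppressive let-7a-5p stood at 42528 ± 1199 against 37456 ± 1302 CPM, and let-7f-5p at 32411 ± 420.0 against 35062 ± 3441 CPM. None of these 5 passed limma (adjusted p = 0.659, 0.916, 0.182, 0.694 and 0.877 in the same order), while miR-16-5p passed DESeq2 as lower (adjusted p = 0.0468). The 10 most abundant miRNAs took 65.5 ± 0.150% of the listed CPM in LINC00673 and 65.8 ± 1.42% in NC libraries (exact permutation p = 0.9). The number of miRNAs detected was 793 ± 96.1 against 696 ± 38.4 (exact permutation p = 0.3), and with all libraries thinned to 211242 reads it was 664 ± 28.7 against 669 ± 13.9 (exact permutation p = 1).

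Between the groups, miR-92a-3p and miR-92b-3p rose in the LINC00673 libraries. The level of miR-92a-3p, a member of the oncogenic miR-17-92 cluster, was 4430 ± 159 CPM in LINC00673 and 2539 ± 369 CPM in NC libraries (SD, n = 3 each), a log2 difference of 0.81 with a standard error of 0.16 (limma adjusted p = 0.0358). Its paralog miR-92b-3p, which shares the seed sequence of miR-92a-3p, was at 245 ± 14.8 against 107 ± 37.1 CPM, a log2 difference of 1.24 with a standard error of 0.26 (limma adjusted p = 0.0392). For both miRNAs, all 3 LINC00673 libraries lay above all 3 NC libraries. The miR-92a-3p arm is encoded by MIR92A1 (chromosome 13, 91351314 to 91351391, exonic in MIR17HG) and by MIR92A2 (chromosome X, 134169538 to 134169612, exonic in a non-coding transcript), and miR-92b-3p by MIR92B (chromosome 1, 155195177 to 155195272, exonic in AC234582.1). The treatment of reads shared by such near-identical arms is not given in the sources used here, so the level of miR-92b-3p is uncertain.

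Of the 810 miRNAs tested with limma, 2 passed as higher and 0 as lower, while 54 higher and 36 lower miRNAs had an unadjusted p under 0.05. On the recovered reads, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment passed 15 higher and 7 lower miRNAs, both limma calls among them, and DESeq2 passed 5 and 10. The 5 higher in DESeq2 were miR-92a-3p, miR-92b-3p, miR-30d-5p, miR-576-5p and miR-23a-3p. The 10 lower were miR-301b-3p, miR-301a-3p, miR-29b-3p, miR-19a-3p, miR-34a-5p, miR-101-3p, miR-769-5p, let-7i-5p, miR-877-5p and miR-16-5p. For every miRNA past edgeR or DESeq2, the edgeR log2 difference lay above that of DESeq2. Values were 0.91 against 0.80 for miR-92a-3p, 0.59 against 0.49 for miR-221-3p and -0.54 against -0.65 for miR-29b-3p. Such an offset favours higher calls in edgeR and lower calls in DESeq2, but its part in these counts was not tested. In 63 miRNAs all LINC00673 libraries lay above all NC libraries and in 62 below, together 15.4% of those tested, against 10% by chance. In limma, both calls were lost when any 1 of the 6 libraries was left out, with an adjusted p of 0.0861 to 0.632 for miR-92a-3p and 0.0651 to 0.632 for miR-92b-3p. In edgeR both miRNAs were past the threshold except without LINC00673 replicate 1 (adjusted p = 0.211) or replicate 3 (adjusted p = 0.102), where 0 of the 810 miRNAs passed. Without NC replicate 3, edgeR passed 36 higher and 13 lower miRNAs.

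**Figure D1:**
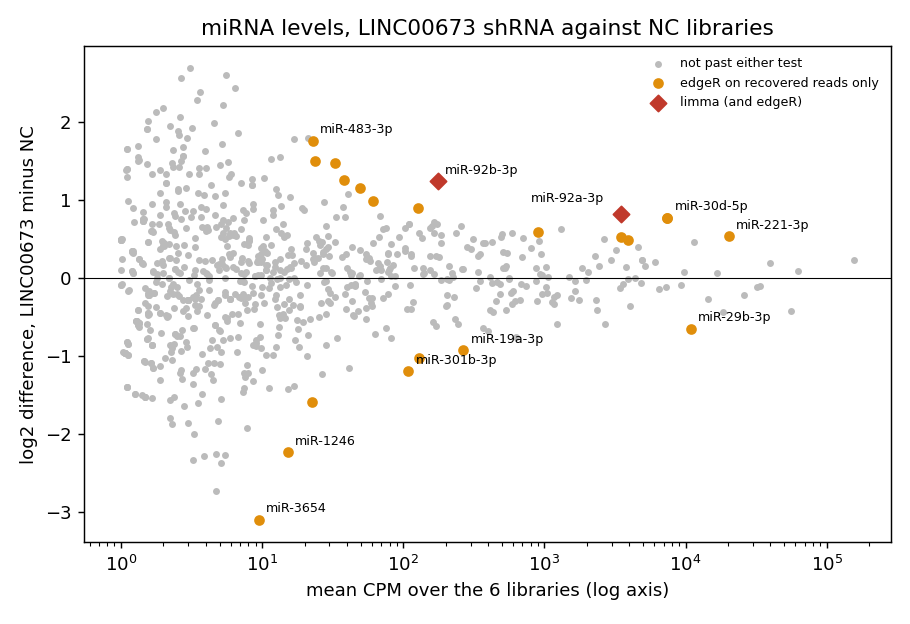
Log2 difference (LINC00673 minus NC, log2(CPM + 1) scale) against the mean CPM over the 6 libraries on a log axis, 1 point per tested miRNA (n = 810). Diamonds mark the 2 miRNAs past limma, orange points those past edgeR on recovered reads only, and the wide scatter at low CPM shows the larger errors of low miRNAs (median standard error 0.95 under 10 CPM and 0.32 at 10 CPM or more).

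Beyond this pair, none of the higher miRNAs with the smallest p passed limma. The level of miR-30d-5p (MIR30D, chromosome 8, 134804876 to 134804945, outside annotated host genes) was 9267 ± 1154 CPM in LINC00673 and 5573 ± 1675 CPM in NC libraries (log2 difference 0.77, limma adjusted p = 0.0571, edgeR adjusted p = 0.000213, DESeq2 adjusted p = 0.0279). The miR-221-3p arm, which targets the cell cycle inhibitor CDKN1B (MIR221, chromosome X, 45746157 to 45746266, intronic in MIR222HG), stood at 23816 ± 1445 against 16939 ± 5058 CPM (0.53, limma adjusted p = 0.182, edgeR adjusted p = 0.0166, DESeq2 adjusted p = 0.164). The level in NC replicate 3 lay within the range of the LINC00673 libraries. The miR-483-3p arm, encoded in an intron of IGF2 (MIR483, chromosome 11, 2134134 to 2134209), was at 35.4 ± 10.6 against 10.6 ± 6.94 CPM (1.76, limma adjusted p = 0.156, edgeR adjusted p = 0.0199). The other 5 were miR-576-5p, miR-1271-5p, miR-93-3p, miR-3144-3p and miR-3615, with log2 differences of 0.89, 1.26, 1.15, 0.99 and 1.48, a limma adjusted p of 0.182 each and an edgeR adjusted p of 0.0199 to 0.0411. For miR-3615 the groups overlapped, with NC replicate 3 at 37.22 CPM above LINC00673 replicate 1 at 31.55 CPM. Of these 5, miR-576-5p passed DESeq2 (adjusted p = 0.0468), miR-93-3p and miR-3144-3p did not (0.112 and 0.116), and DESeq2 gave no adjusted p for miR-1271-5p, miR-3615 or miR-483-3p. Outside the naming rule, and chosen after their values were seen, miR-125a-5p, miR-26a-5p, miR-484, miR-31-5p and miR-10a-5p were also past edgeR in this direction (adjusted p = 0.00347, 0.0338, 0.0411, 0.0411 and 0.0413). None of these passed limma (adjusted p = 0.182 to 0.195). In DESeq2 miR-484 had no adjusted p and the others did not pass (adjusted p = 0.0527 to 0.324). For miR-125a-5p, NC replicate 1 (8458 CPM) lay above LINC00673 replicates 2 and 3 (7796 and 8419 CPM). For the others, every LINC00673 library lay above every NC library.

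Among the lower miRNAs, none passed limma. The smallest p belonged to miR-301b-3p, of the family of miR-130 and miR-301 (MIR301B, chromosome 22, 21652981 to 21653058, intronic in AP000553.1), at 65.7 ± 11.5 CPM in LINC00673 and 152 ± 18.97 CPM in NC libraries (log2 difference -1.20, limma adjusted p = 0.0571, edgeR adjusted p = 0.0108, DESeq2 adjusted p = 0.00594). Its paralog miR-301a-3p was at 468 ± 91.9 against 793 ± 135 CPM (-0.76, limma adjusted p = 0.0943, edgeR adjusted p = 0.0579, DESeq2 adjusted p = 0.0341). The collagen-targeting miR-29b-3p, from MIR29B1 (chromosome 7, 130877459 to 130877539, exonic in LINC-PINT) and MIR29B2 (chromosome 1, 207802443 to 207802523, exonic in MIR29B2CHG), was at 8475 ± 1059 against 13325 ± 1571 CPM (-0.65, limma adjusted p = 0.0571, edgeR adjusted p = 0.0411, DESeq2 adjusted p = 0.0143). A further member of the miR-17-92 cluster, miR-19a-3p (MIR19A, chromosome 13, 91350891 to 91350972, exonic in MIR17HG), was at 184 ± 34.3 against 348 ± 30.5 CPM (-0.93, limma adjusted p = 0.0571, edgeR adjusted p = 0.0299, DESeq2 adjusted p = 0.00799). The p53-induced miR-34a-5p (MIR34A, chromosome 1, 9151668 to 9151777, exonic in MIR34AHG) was at 976 ± 36.9 against 1468 ± 62.2 CPM (-0.59, limma adjusted p = 0.156, edgeR adjusted p = 0.197, DESeq2 adjusted p = 0.00518). In all 5 of these, every LINC00673 library lay below every NC library.

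Also named by the rule, miR-101-3p, miR-769-5p and let-7i-5p had log2 differences of -0.60, -0.68 and -0.44 and passed DESeq2 (adjusted p = 0.0279 each) but neither limma (adjusted p = 0.156, 0.182 and 0.182) nor edgeR (adjusted p = 0.133, 0.163 and 0.302). The mirtron miR-877-5p, from an intron of ABCF1, was at 81.6 ± 20.48 CPM in LINC00673 and 177 ± 85.8 CPM in NC libraries (-1.03, limma adjusted p = 0.182, edgeR adjusted p = 0.0177, DESeq2 adjusted p = 0.0468), and its log2 difference was -0.66 without NC replicate 2. The level of miR-1246, whose reads are shared with U2 small nuclear RNA, was 4.84 ± 1.97 against 25.6 ± 4.88 CPM (-2.23, limma adjusted p = 0.0715, edgeR adjusted p = 0.0179, no adjusted p in DESeq2), near the floor of 3 reads in the LINC00673 libraries. Outside the rule, and chosen after their values were seen, miR-3654 and miR-663a were also past edgeR as lower (adjusted p = 0.0166 and 0.0204). Neither passed limma (adjusted p = 0.0625 and 0.222), and DESeq2 gave no adjusted p for them. The level of miR-3654 was 1.33 ± 1.35 against 17.7 ± 7.70 CPM, under the floor of 3 reads in every LINC00673 library. For miR-663a the groups overlapped (LINC00673 replicate 2 at 10.78 and NC replicate 1 at 10.35 CPM), and NC replicate 2 stood at 64.22 CPM.

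**Figure D2:**
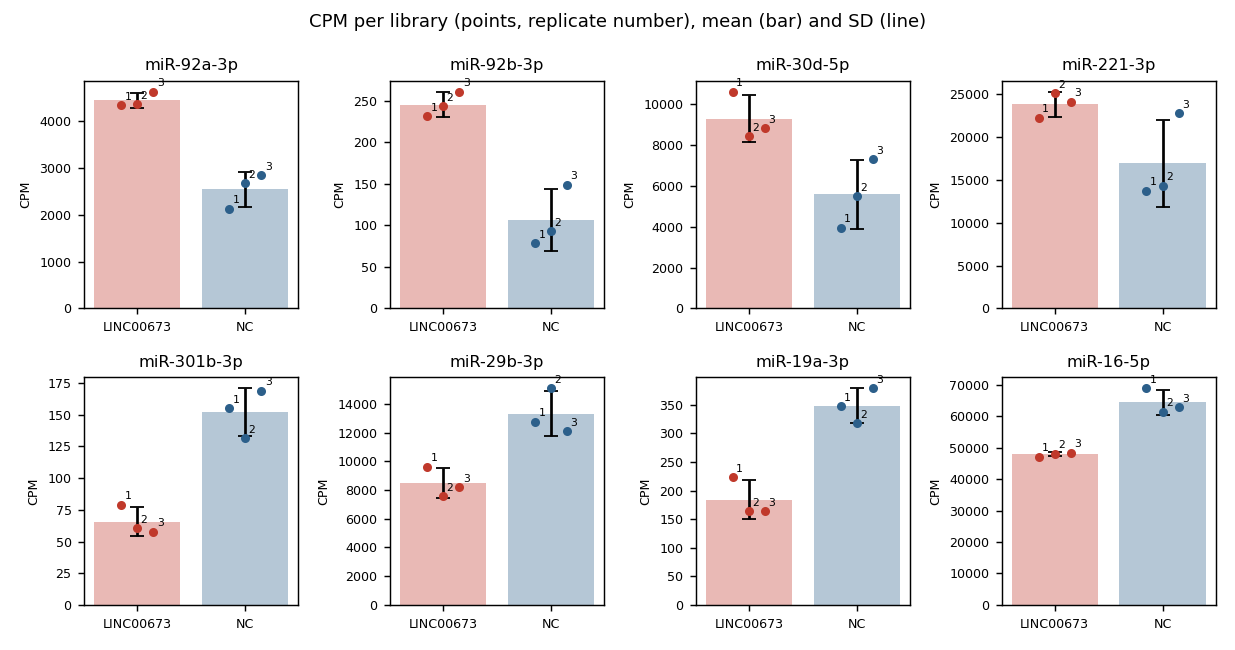
CPM of 8 miRNAs in each library (points, numbered by replicate), with group means (bars from 0) and SD (lines), n = 3 per group. The LINC00673 libraries lay above all NC libraries for miR-92a-3p, miR-92b-3p and miR-30d-5p and below them for miR-301b-3p, miR-29b-3p, miR-19a-3p and miR-16-5p, while for miR-221-3p NC replicate 3 lay among the LINC00673 libraries.

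Among the 20 lists, the 14q32 imprinted cluster was higher in the LINC00673 libraries. This is a large cluster of maternally expressed miRNA genes in the DLK1-DIO3 region. The log2 difference was above 0 for 32 of its 38 tested members, with a median of 0.55 (camera adjusted p = 0.0027, and adjusted p = 0.21 with an estimated correlation). Its summed level was 1260 ± 125 CPM in LINC00673 and 909 ± 121 CPM in NC libraries (SD, n = 3 each, exact permutation p = 0.1, the smallest possible). No member passed limma, with 0 over all miRNAs tested and 0 adjusted over the list alone. In 6 members all LINC00673 libraries lay above all NC libraries, and in 1 below, against 15.4% separated in either direction over all miRNAs tested. Of the 6, miR-299-5p and miR-380-5p were listed at 0 in all NC libraries, where the floor of 3 reads was 6.21 to 10.1 CPM. The 1 below, miR-655-3p, was under this floor too (0.89 against 2.89 CPM). With a minimum of 10 CPM, 16 of the 38 members remained. Examples were miR-379-5p (chromosome 14, 101022066 to 101022132, intronic in MEG8) at 205 ± 39.8 against 127 ± 37.7 CPM (log2 difference 0.72, and 0.45 without NC replicate 3, limma adjusted p = 0.255) and miR-409-3p at 188 ± 16.9 against 121 ± 19.6 CPM (0.64, limma adjusted p = 0.263), whereas miR-382-5p was at 183 ± 30.4 against 188 ± 42.3 CPM. At the preset correlation the list was not past the threshold in edgeR without NC replicate 3 (camera adjusted p = 0.0535, against a range of 0.000883 to 0.0535 over 29 alternative fits). These 29 fits do not include the estimated correlation or limma's fry test, and the list passed neither (fry adjusted p = 0.0631).

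The mesenchymal and stromal list was the other that passed camera as higher, with 18 of 27 tested members above 0 and a median of 0.23 (adjusted p = 0.0239, and adjusted p = 0.66 with an estimated correlation). None of its members passed limma, with 0 adjusted over the list alone, while edgeR passed miR-221-3p and miR-31-5p. In 3 members all LINC00673 libraries lay above all NC libraries, and in 2 below. The 2 below were miR-199a-5p (194 ± 10.7 CPM in LINC00673 and 293 ± 29.5 CPM in NC libraries) and miR-100-3p (453 ± 42.7 against 613 ± 146 CPM). The level of miR-125b-5p was 13185 ± 765 CPM in LINC00673 and 9943 ± 3587 CPM in NC libraries (log2 difference 0.46, limma adjusted p = 0.304). NC replicate 1 lay above all LINC00673 libraries for miR-125b-5p, and the log2 difference was 0.74 without it and 0.29 without NC replicate 3. The level of miR-31-5p was 1076 ± 130 against 725 ± 164 CPM. The list took 31.3% to 34.4% of the listed CPM in the LINC00673 libraries, 24.3% and 26.8% in NC replicates 1 and 2, and 33.7% in NC replicate 3 (exact permutation p = 0.3). With limma's values the call was lost without LINC00673 replicate 2 or 3 or NC replicate 1 or 2 (camera adjusted p = 0.192, 0.116, 0.372 and 0.232, with a range of 3.4e-05 to 0.372 over 29 alternative fits). It was also lost with a minimum of 10 CPM, rescaling without the 10 most abundant miRNAs, quantile normalization, thinned reads, the GC trend removed, and LINC00673 replicates 2 and 3 averaged (camera adjusted p = 0.0664, 0.0601, 0.131, 0.0507, 0.0637 and 0.145). The list did not pass limma's fry test either (fry adjusted p = 0.404).

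**Figure D3:**
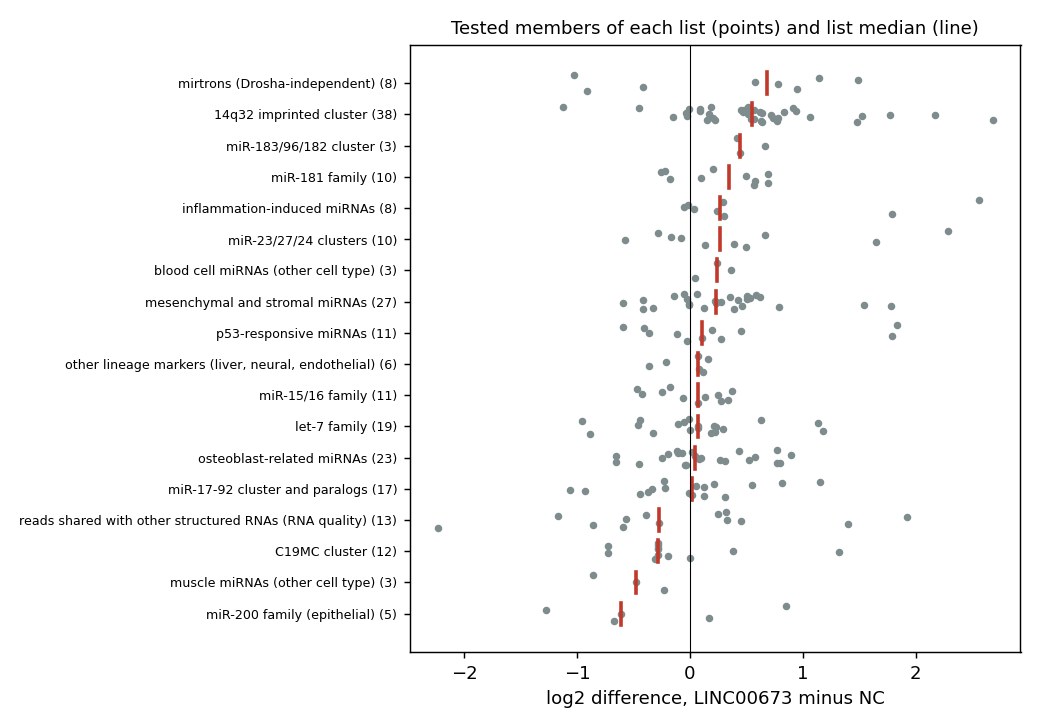
Log2 differences (LINC00673 minus NC, log2(CPM + 1) scale) of the tested members of each list with at least 3 tested members (points, number of members in parentheses) and the list median (vertical line). The 14q32 imprinted cluster has a median of 0.55 and the mesenchymal and stromal list one of 0.23; both passed camera at the preset correlation only.

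The other 16 lists tested did not pass camera. The miR-17-92 cluster and its paralogs, with 17 tested members, held 1 riser in limma, miR-92a-3p, and adjusted over the list alone 2 higher members (miR-92a-3p and miR-93-3p) and 1 lower (miR-19a-3p). Its most abundant members miR-93-5p and miR-25-3p stood at 24051 ± 2489 against 28215 ± 3858 CPM and at 16932 ± 1658 against 16293 ± 2032 CPM. Of the 23 osteoblast-related miRNAs tested, 0 passed over all miRNAs, and adjusted over the list alone miR-26a-5p and miR-30d-5p passed as higher and miR-29b-3p and miR-218-5p as lower. Of the 11 p53-responsive miRNAs, only miR-34a-5p passed adjusted over the list alone, as lower, while miR-192-5p was at 706 ± 89.9 against 767 ± 137 CPM and miR-107 at 67.9 ± 9.53 against 72.2 ± 29.5 CPM. Of the 10 members of the miR-23/27/24 clusters, miR-23a-3p (3072 ± 243 against 2183 ± 298 CPM) and miR-27a-5p (312 ± 35.1 against 198 ± 35.9 CPM) passed as higher adjusted over the list alone. The same was true of miR-183-5p among 3 members of its cluster (197 ± 18.6 against 124 ± 7.07 CPM), and of miR-132-5p and miR-212-5p among 8 inflammation-induced miRNAs, where miR-212-5p was listed at 0 in all NC libraries. Its log2 difference of 2.56 rests on these values of 0, and the floor of 3 reads in the NC libraries was 6.21 to 10.1 CPM. In edgeR, 0 members of the miR-23/27/24, miR-183 and inflammation-induced lists passed. In the list of 8 mirtrons and other miRNAs made without Drosha, miR-484 passed as higher and miR-877-5p as lower adjusted over the list alone. Of these, miR-877-5p comes from an intron, whereas the miR-484 gene is exonic in NDE1. The camera adjusted p was 0.143 for the cluster of miR-183, miR-96 and miR-182, 0.151 for the miR-181 family, 0.214 each for the miR-23/27/24 clusters and the inflammation-induced miRNAs, and 0.551 to 0.966 for the other 12 lists.

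Neither limma nor its adjustment over the list alone passed a member in the let-7 (19 tested), miR-15/16 (11), miR-181 (10), miR-200 (5), C19MC (12), muscle (3), blood cell (3) and other lineage (6) lists. Of the epithelial miR-200 family, miR-200c-3p was at 5.33 ± 4.83 CPM in LINC00673 and 9.79 ± 3.66 CPM in NC libraries. The muscle miRNA miR-206 was at 36.2 ± 1.93 against 52.5 ± 16.9 CPM, the blood cell miRNA miR-142-3p at 166 ± 15.3 against 165 ± 49.1 CPM, the endothelial miR-126-3p at 3503 ± 478 against 4523 ± 910 CPM and the neural miR-9-5p at 2073 ± 60.1 against 1974 ± 144 CPM. The miR-181 family was represented by miR-181b-5p (363.2 ± 18.2 against 257 ± 22.3 CPM) and C19MC by miR-516a-5p (414 ± 40.2 against 412 ± 12.3 CPM). Of 13 names that share reads with other structured RNAs, miR-1246 and miR-3648 passed as lower adjusted over the list alone, and miR-3648 was at 25.2 ± 8.49 against 57.2 ± 15.2 CPM. Both arms of hypoxia-induced miR-210 were tested without passing limma, with miR-210-3p at 211 ± 6.57 against 157 ± 25.1 CPM (log2 difference 0.44, adjusted p = 0.509). For the let-7 and miR-15/16 families the median and mean log2 difference were above 0 and camera's direction was down. For the miR-17-92 and other lineage lists the median was above 0 while the mean and camera's direction were below.

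In a principal component analysis of the 362 miRNAs with a mean of at least 10 CPM, the first component (35.6% of variance) placed NC replicate 3 at -4.19, among the LINC00673 libraries (-4.22 to -3.81) and apart from NC replicates 1 and 2 (8.63 and 7.66). On the third component (19.1% of variance) NC replicate 3 lay at -7.74, apart from the LINC00673 libraries (1.85 to 3.28). NC replicates 1 and 2 lay there at -3.58 and 3.74. By chi-square per degree of freedom, NC replicate 3 differed from the LINC00673 libraries by 19.8 to 20.6. From NC replicates 1 and 2 it differed by 55.9 and 26.4.

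**Figure D4:**
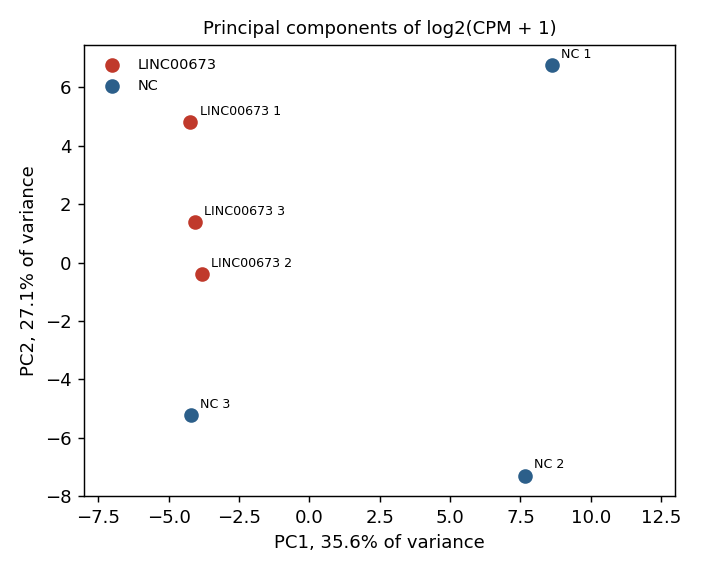
First and second principal components of log2(CPM + 1) for the 6 libraries (362 miRNAs), which carry 35.6% and 27.1% of the variance. NC replicate 3 lies at the level of the LINC00673 libraries on the first component and at -5.24 on the second, below the LINC00673 libraries (-0.41 to 4.82).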

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

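The alternatives chosen after the data were seen were thinned reads, GC trend removal, LINC00673 replicates 2 and 3 treated as 1 sample, merged identical miRNAs, edgeR without each library in turn, and every alternative for clusters of neighbouring genes. Over 1418 values of 49 named miRNAs under the alternatives, 1262 kept their direction and their side of the threshold, 113 came to pass it, 28 no longer passed and 15 changed sign. For miR-92a-3p the log2 difference ranged from 0.69 to 1.01 and for miR-92b-3p from 1.05 to 1.64, and each was past the threshold under 15 of 29 alternatives. Of 18 lists, the 14q32 imprinted cluster was past camera at the preset correlation under 28 of 29 alternative fits (adjusted p from 0.000883 to 0.0535) and the mesenchymal and stromal list under 19 of 29 (adjusted p from 3.4e-05 to 0.372). In the simulation limma recovered 25.5% and edgeR 59.6% of 2-fold changes at 10 CPM or more, and each 0% below. Its counts followed edgeR's own dispersion trend, so these values do not rank limma and edgeR on the real data.

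In limma, 2 miRNAs were higher, 0 lower and 2 lists past the threshold. The number higher was 0 with a pseudocount of 0.5, with a minimum of 10 CPM, with quantile normalization, without the intensity trend, with thinned reads and with LINC00673 replicates 2 and 3 averaged. It was 4 without the filter and 4 with the robust prior. The number lower was 5 with a pseudocount of 5, 7 without the filter, 1 with median-of-ratios rescaling, 3 with rescaling without the 10 most abundant miRNAs, 6 with the robust prior and 2 with the GC trend removed. The number of lists was 1 with a minimum of 10 CPM, rescaling without the 10 most abundant, quantile normalization, thinned reads, the GC trend removed or replicates 2 and 3 averaged, and in each of these the mesenchymal and stromal list was lost. It was 0 with an estimated correlation and 0 with fry. edgeR called 15 higher and 7 lower and DESeq2 5 and 10, and edgeR with replicates 2 and 3 summed 4 and 1. Of the clusters of neighbouring genes, 2 passed camera in limma, against 1 with a minimum of 10 CPM, 4 with thinned reads, 6 in edgeR, 4 in DESeq2, 0 with an estimated correlation and 3 with fry. The cause of these changes was not tested.

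Leaving out 1 library gave 0 to 36 higher and 0 to 13 lower miRNAs, 1 to 3 lists and 1 to 5 clusters of neighbouring genes over limma and edgeR. The cluster of MIR379 to MIR369 was lost in edgeR without NC replicate 3 (adjusted p = 0.102, against a range of 0.00201 to 0.468 over 31 alternatives). In limma the clusters past camera numbered 4 without NC replicate 3 and 1 without any other library. In edgeR they numbered 1, 2 and 2 without LINC00673 replicates 1, 2 and 3 and 1, 5 and 4 without NC replicates 1, 2 and 3. In limma 0 miRNAs passed without any 1 of the 6 libraries, with 51 to 137 at an unadjusted p under 0.05. In edgeR 0 miRNAs passed without LINC00673 replicate 1 or 3 (82 and 69 at an unadjusted p under 0.05). Without LINC00673 replicate 2 the counts were 4 and 1, without NC replicate 1 they were 6 and 8, without NC replicate 2 they were 5 and 2, and without NC replicate 3 they were 36 and 13. The replicate block gave 2 higher, 0 lower, 2 lists and 2 clusters. Deviations of libraries with the same replicate number correlated at 0.12, 0.15 and 0.03 across miRNAs, so the numbers were not taken to pair the samples, although each LINC00673 library correlated best with the NC library of its own number.

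The difference in the share of the 10 most abundant miRNAs (-0.31 percentage points) changed sign for the top 3 (0.54) and the top 50 (0.19), and without NC replicate 3 (range -0.92 to 0.47). The difference in miRNAs detected (97.3) changed sign at 10 CPM (-8.67) and in thinned reads (-5.33), and a minimum above 0 CPM was the same as 1 CPM, since 1 read exceeded 1 CPM in every library. The log2 difference of miR-382-5p (-0.03) turned positive with thinned reads (0.20), in edgeR (0.063), in edgeR with replicates 2 and 3 summed (0.016) and without some libraries (range -0.22 to 0.17). That of miR-20a-5p (0.12) turned negative with quantile normalization (-0.013) and without NC replicate 1 (range -0.19 to 0.58). That of let-7f-5p (-0.11) ranged from -0.18 to 0.046 without 1 library, and was positive in edgeR without LINC00673 replicate 2 or NC replicate 2. The cause was not tested for these.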

Other observations

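The tests of a mislabelled library, of mixing and of a whole-cluster change, the values from held-out libraries and the tests of clusters of neighbouring genes with their alternatives were chosen after the result was seen. Of 41 clusters of neighbouring miRNA genes with at least 3 tested arms, 2 passed camera as higher in the LINC00673 libraries. All tested members of both belonged to the 14q32 or the mesenchymal and stromal list, so these calls restated the list results and 0 clusters outside those lists passed camera in limma (8 of the 41 were at an unadjusted p under 0.05, and 6 passed in edgeR). The first ran from MIR379 to MIR369 (chromosome 14, 101022066 to 101065667) and held the 38 tested members of the 14q32 list (camera adjusted p = 0.00615, and adjusted p = 0.468 with an estimated correlation). The second ran from MIR221 to MIR222 (chromosome X, 45746157 to 45747124), with 4 of 4 tested arms above 0 and a median log2 difference of 0.52 (camera adjusted p = 0.0147, and adjusted p = 0.715 with an estimated correlation). Its arms miR-221-5p and miR-222-3p stood at 1547 ± 397 against 1085 ± 608 CPM and at 3595 ± 429 against 2877 ± 864 CPM. For both and for miR-221-3p, NC replicate 3 lay within the range of the LINC00673 libraries, so the difference of these 3 arms rested on NC replicates 1 and 2, whereas for miR-222-5p (159 ± 24.6 against 111 ± 4.59 CPM) all NC libraries lay below all LINC00673 libraries. The call was lost in limma without LINC00673 replicate 1, 2 or 3 or NC replicate 1 or 2 (adjusted p = 0.128, 0.0846, 0.0669, 0.299 and 0.265) and not without NC replicate 3 (adjusted p = 0.00216), with a range of 1.4e-06 to 0.715 over 31 alternatives. The cluster of MIR132 and MIR212 had 3 of 3 arms above 0 and a median of 1.79 without passing (camera adjusted p = 0.0612). This median was the value of miR-132-5p, which ranged from 1.26 to 2.71 in limma without 1 library. A shift in the use of the 5p and 3p arms was tested for 80 precursors with both arms at 10 CPM or more, and 0 passed in limma, with 7 at an unadjusted p under 0.05. The smallest p was that of miR-93, whose log2 ratio of 5p to 3p was 8.45 in LINC00673 and 9.83 in NC libraries (limma adjusted p = 0.498).

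The rise of miR-92a-3p and miR-92b-3p was weighed against 3 technical explanations. Removing each library's trend on estimated arm GC left a mean log2 difference of 0.92 for the pair (1.03 before). That trend thus did not account for the rise of the pair. The estimate comes from the precursor rather than the mature sequence, so an effect of mature GC content was not tested. Thinning to equal depth left 1.07. Random thinning keeps the expected share of each miRNA, so it could not decide on an effect of depth. Neither miRNA passed limma in the thinned reads (adjusted p = 0.261 each). The share of miR-92b-3p in the reads of the pair was 5.08%, 5.30% and 5.35% in the LINC00673 libraries and 3.57%, 3.38% and 4.99% in the NC libraries, and although each LINC00673 share exceeded each NC share, a common share was narrowly not excluded (chi-square p = 0.0504). Spill-over of miR-92a-3p reads into the miR-92b-3p row thus stays open, and the pair may be 1 observation rather than separate ones. An effect of the shRNA or of LINC00673 depletion also stays open.

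The first principal component placed NC replicate 3 with the LINC00673 libraries. Of 92 miRNAs chosen from LINC00673 against NC replicates 1 and 2, 64.1% (59, 95% exact binomial interval 53.5% to 73.9%, too narrow because miRNAs are not independent) lay nearer to the LINC00673 mean in NC replicate 3, against 29.6% and 28.6% when NC replicates 1 and 2 were held out in the same way and 78.0%, 88.2% and 98.3% for the held-out LINC00673 libraries. The bounds, a share over 80% for a wrong label and 50% or less against one, were chosen with the first component already seen, and this share lies between them, so a wrong label can be neither shown nor excluded. Mixing of LINC00673 material into this library needs 1 common fraction, and the position of 26 abundant miRNAs between the groups had an interquartile range of 0.785, but held-out LINC00673 replicate 1 and NC replicate 1 reached 0.864 and 1.40, so this range does not exclude mixing either. GC content remained undecided (Spearman rho = 0.1002 across miRNAs, which are not independent replicates).

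Within the miR-17-92 cluster, whose miRNAs are cut from 1 transcript, miR-92a-3p and miR-19a-3p lay on opposite sides of 0. The log2 ratio of miR-92a-3p to miR-19a-3p was 4.60 ± 0.29 in LINC00673 and 2.86 ± 0.23 in NC libraries (SD, n = 3 each), with no test of its own, since each miRNA had been picked for its separation. The 4 main arms not picked for the contrast had a median log2 difference of -0.35 (SD 0.26, range of the median over alternatives -0.40 to -0.19). This argues against a rise of the whole cluster as the source of the miR-92a-3p difference (0.81). The contrast was 1.73 after removal of the estimated GC trend and 1.74 before, so that trend did not account for it. The GC content of the mature sequences was not tested. Extra miR-92a-3p from the X-linked copy could not be tested as planned. Of the members that the X-linked cluster does not share with the miR-17-92 cluster, 0 passed the filter. The 2 of them that were listed reached at most 3.21 CPM, against a difference of 1891 CPM in miR-92a-3p. The arm miR-19b-3p was tested but is encoded in both clusters. Processing or stability of single cluster members is a candidate explanation that these data did not test.

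For the count of miRNAs past limma, 1 of the 10 splits of the 6 libraries, the real one, gave 2 or more calls, and the highest of the other splits gave 0 (22 and 1 in edgeR). With 10 splits a share under 0.05 cannot be reached.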
